A study of Mus musculus with 6 samples.

How the data were processed

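Total RNA of 6 mouse brain tumors, 3 with a guide RNA against Ptk2 and 3 with a control guide against TIGRE, was extracted with Trizol and cleaned on RNeasy columns, depleted of ribosomal RNA and made into directional libraries with the NEBNext Ultra II kit, per the labels' protocols. STAR, DESeq2 and the genome build GRCm39 are named per the submitters' processing notes, with no versions or roles. The tool that counted reads, its strand setting and the gene annotation are not given in the sources used here. Overlapping and antisense genes can therefore share reads.

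The deposited table holds a signal per gene and library, each library's counts divided by 1 size factor, as the values themselves show. All values of a column are whole multiples of its smallest step (100% of 157136 values above 0, within 0.001 reads). Reads were recovered by dividing by that step, and 1 read was worth 0.58 to 0.94 in 5 libraries and 3.82 in sgPtk2 tumor 2. The recovered totals were 1669353 reads in that library and 5515714 to 9377617 in the others. Values were not scaled to gene length. The table has 149132 rows for 57180 gene IDs, of which 21156 are repeated in identical rows and were used once, and 525 have no symbol. The intervals given cover spread between genes only.

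Columns were matched to tumors by the labels. For the sgPtk2 tumors the number in the column name differs from that in the title, and the titles' numbers are used. No pair of replicates agreed within sampling noise (chi-square per degree of freedom 14.9 to 82.6). That noise covers read sampling only, so this does not show that the tumors are independent samples. Each library counts as 1 sample, as labeled.

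Before the data were examined, edgeR's quasi-likelihood test on counts had been fixed as the main test. Because the deposited values are normalized, limma (version 3.58.1, with trend) on log2(value + 1) became the main test, with genes kept by filterByExpr on the recovered reads (16943 genes) and Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which can understate changes of low genes. Few or no reads in 1 library can also overstate them. Hdc of the neutrophil list was at -1.24 with 6 libraries and 0.12 without sgPtk2 tumor 2. edgeR (4.0.16) and DESeq2 (1.42.0) on the recovered reads were added as alternatives, and the report gives the number of genes each called. DESeq2 tested 35397 genes and gave no adjusted p to 16637 of them.

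The 40 gene lists and the rule for named genes were fixed with that plan. The lists covered signaling near focal adhesion kinase, the cell cycle, matrix, cell types of brain and blood, immune responses, metabolism and RNA quality, and 5 of their 897 entries had no row in the table. The lists and the genes of each chromosome were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes were Ptk2, its paralog and the genes of the genotype, then 10 genes of each direction with separate groups, a mean of at least 1 CPM and a symbol that is not a model name, filled by the smallest p where too few passed, and up to 4 members per list by the smallest p. Genes outside it are said to have been chosen after their values were seen.

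The annotation at hand, GENCODE M21 on GRCm38, differs from the build of the submitters, so no coordinates are printed. It gave chromosome, gene order, GC content and transcript length for the 51884 IDs it shares with the table. Steps along chromosomes are differences of medians, with 2000 bootstrap draws over genes, and boundaries are the places with the largest rank-sum statistic.

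The fits were tested on simulated data with known fold changes in 200 of the 16943 genes of the comparison of sgPtk2 with sgTIGRE. With 6 libraries limma recovered 0% of genes changed 1.5-fold, 5.97% of 2-fold and 54.5% of 4-fold, and called 2 unchanged genes. With 5 libraries it recovered 4.48%, 17.9% and 71.2% and called 8 unchanged genes. DESeq2 with 6 libraries recovered 1.49%, 14.9% and 81.8% and called 35 unchanged genes. A list of 24 genes shifted by 0.6 (log2) was called in 20 of 20 runs, with 0 calls among 780 unshifted lists. The simulated genes varied independently of each other, so this does not show how often correlated lists are called falsely. Estimated correlations of the real lists reached 0.72, for the mitosis list. A simulated chromosome step of 0.4 was placed within 5 genes in 37 of 60 cases.

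Alternatives covered the pseudocount, the scaling, the filter, the test, library weights, a block by tumor number, each library left out in turn, abundant noncoding RNA left out and running medians of neighboring genes removed. Python 3.11.15 and R 4.3.3 were used.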

Results

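RNA was sequenced from 6 mouse brain tumors of a Trp53, Pten and Rb1 null genotype, 3 with a guide RNA against Ptk2 and 3 with a control guide against TIGRE. Ptk2 encodes focal adhesion kinase, a cytoplasmic tyrosine kinase that relays signals from integrins. TIGRE is an intergenic locus on chromosome 9 that serves as a neutral target. The labels number the tumors within each group but do not say whether they came from separate animals, litters or a shared cell source. The p-values therefore measure only the spread between these tumors, which may be technical.

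The libraries held 9377617, 7095276 and 7799165 gene-assigned reads in sgTIGRE tumors 1, 2 and 3, and 5515714, 1669353 and 6910997 in sgPtk2 tumors 1, 2 and 3. The library of sgPtk2 tumor 2 stood apart from the other 5. The nuclear noncoding RNA 7SK took 18.5% of its reads, against 2.34% to 4.66% in the others, and 18S ribosomal RNA took 3.83% against 0.050% to 0.13%. Protein-coding genes held 70.6% of its reads, and 19018 genes had at least 1 read, against 26851 to 29406 in the others. Across genes, which are not independent replicates, its log2 values correlated with those of the other tumors at a Pearson's r of 0.82 to 0.85, and the other tumors correlated with each other at 0.92 to 0.97.

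**Figure D1:**
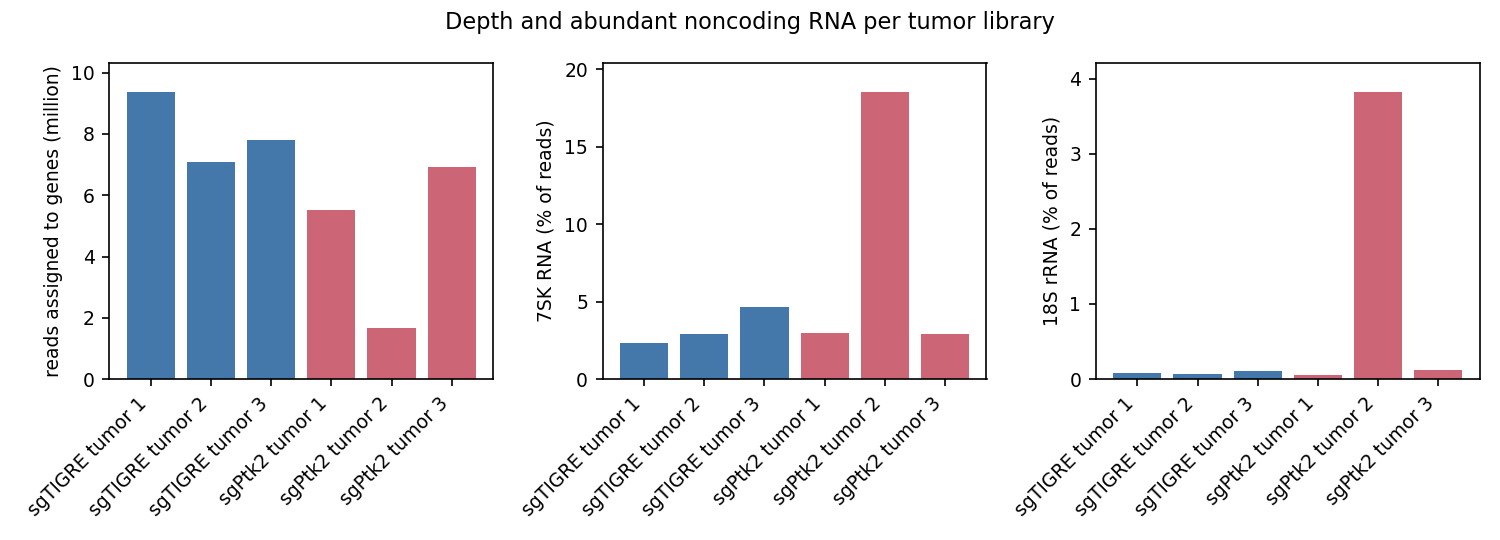
Bars give, for each of the 6 tumor libraries on the x axis, the reads assigned to genes (left), the percent of reads from 7SK RNA (middle) and the percent from 18S rRNA (right), with sgTIGRE in blue and sgPtk2 in red. sgPtk2 tumor 2 has the fewest reads, 1669353, and the highest shares of 7SK, 18.5%, and 18S, 3.83%.

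The comparison of sgPtk2 with sgTIGRE tumors addresses how gene expression differs when Ptk2 is ablated in these tumors. Ptk2 itself (on chromosome 15) was lower in each sgPtk2 tumor than in any sgTIGRE tumor. Its normalized read count was 451 ± 78.8 in sgPtk2 and 749 ± 27.5 in sgTIGRE tumors (mean ± SD, n = 3 each). The single values were 402, 542 and 409.6 in sgPtk2 tumors 1, 2 and 3 against 751, 776 and 721 in the sgTIGRE tumors. The log2 fold change of -0.74 (SE 0.18) did not pass the threshold over all genes (limma, adjusted p = 0.21). It passed without sgPtk2 tumor 2 (-0.88, limma, adjusted p = 0.031) and with all 6 libraries in DESeq2 (-0.75, adjusted p = 0.016). On simulated data with 6 libraries DESeq2 called more unchanged genes than limma did. A guide that shifts the reading frame need not lower the mRNA, so this level checks the labels only in part. Genes on either side of Ptk2 on chromosome 15 also differed between the groups, as given with the chromosomes.

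Ptk2b encodes PYK2, the paralog of focal adhesion kinase. Its count was 162 ± 25.4 in sgPtk2 and 83.3 ± 28.5 in sgTIGRE tumors (log2 fold change 1.00, SE 0.31, n = 3 each), with no overlap of the groups, and it did not pass (limma, adjusted p = 0.31). Transcripts of the 3 genes of the null genotype were counted in both groups at similar levels. Trp53 was at 78.1 ± 23.1 in sgPtk2 and 70.2 ± 7.73 in sgTIGRE tumors, Pten at 712 ± 143 and 694 ± 83.9, and Rb1 at 229 ± 22.2 and 211 ± 26.4. Their log2 fold changes were 0.12, 0.025 and 0.12, with limma adjusted p of 0.86, 0.96 and 0.77. The sign turned for Trp53 without sgPtk2 tumor 2 (-0.099), and for Pten without sgTIGRE tumor 3 (-0.079), without sgPtk2 tumor 3 (-0.11) and under TMM scaling (-0.020).

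**Figure D2:**
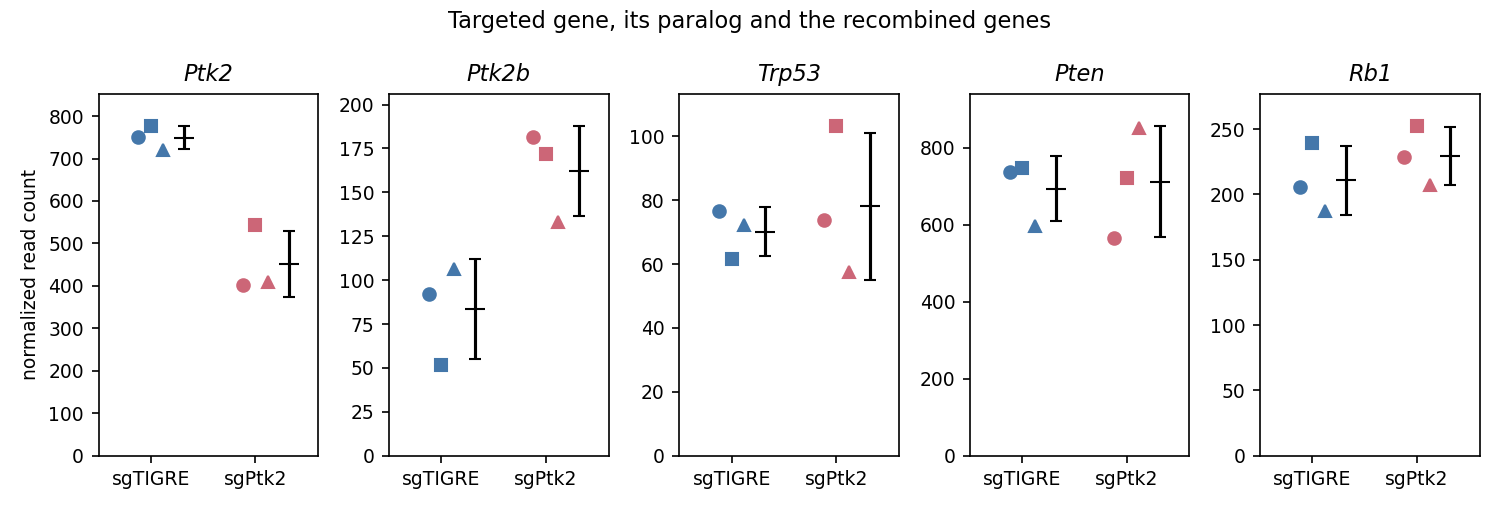
Normalized read counts (y axes, each from 0) of Ptk2, Ptk2b, Trp53, Pten and Rb1 in sgTIGRE (blue) and sgPtk2 (red) tumors, where circles, squares and triangles are tumors 1, 2 and 3 and black bars give the mean ± SD. For Ptk2 the sgPtk2 tumors lie between 402 and 542 and the sgTIGRE tumors between 721 and 776.

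No single gene passed the threshold with all 6 libraries, so the genes named here had the smallest p of each direction and are not past the threshold. Among genes higher in sgPtk2 tumors, Nectin3, a cell adhesion molecule, was at 883 ± 148 against 269.9 ± 7.89 (log2 fold change 1.69, SE 0.18). Nlrc5, the activator of MHC class I transcription, was at 1104 ± 51.7 against 407 ± 66.1 (1.45, SE 0.18). Trib2, which encodes a pseudokinase, was at 499.5 ± 14.6 against 199.7 ± 27.1, and Nyap2, a phosphoinositide 3-kinase adaptor of neurons, at 455 ± 206 against 65.4 ± 6.67. Cacna1c, an L-type calcium channel subunit, Ap1s2, a clathrin adaptor subunit, the transcription factor Onecut2 and the protocadherins Pcdh19 and Pcdhb6 had log2 fold changes of 1.43, 1.09, 1.57, 1.41 and 1.77. Igkv1-117, an immunoglobulin variable segment, was at 80.3 ± 63.7 against 1.4 ± 1.94. Its reads and those of Pcdhb6 are uncertain because close relatives can share them.

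Among genes lower in sgPtk2 tumors, Stag3, a subunit of meiotic cohesin, was at 214 ± 26.5 against 772 ± 131 (log2 fold change -1.84, SE 0.19). Postn, which encodes the matrix protein periostin, was at 131 ± 20.1 against 449 ± 68.1 (-1.77, SE 0.21). Cdkn1c, the cyclin-dependent kinase inhibitor p57, was at 919.8 ± 172 against 2774 ± 349, and Phgdh, the first enzyme of serine synthesis from glucose, at 85.4 ± 9.88 against 238 ± 4.52. The ephrin receptor gene Epha10, the sarcomere gene Mypn, the acyltransferase gene Mogat1 and Calml4 had log2 fold changes of -2.26, -2.07, -2.26 and -2.73. S100a16 and Fam169a had log2 fold changes of -1.77 and -1.79. Each of these 20 genes had separate groups, with no overlap between the 3 sgPtk2 and the 3 sgTIGRE values, because the rule for named genes required it.

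With all 6 libraries, limma put 0 of 16943 genes past an adjusted p of 0.05, with 2068 genes at an unadjusted p under 0.05. The smallest adjusted p was 0.092, and 15 genes, 4 higher and 11 lower, were under 0.1. edgeR on the recovered reads also called 0 genes (2156 unadjusted). The smallest edgeR adjusted p was 0.050003, just above the threshold, and 71 genes, 30 higher and 41 lower, were under 0.1. DESeq2 called 574, of which 302 were higher and 272 lower. Leaving out sgPtk2 tumor 2 gave 168 genes in limma, 53 higher and 115 lower, and the 20 genes above were each past the threshold there (adjusted p 0.0022 to 0.042). Those 20 were chosen by their p in a fit that holds the same 5 libraries, so this is no independent check of them. Leaving out sgPtk2 tumor 3 gave 4. DESeq2 with 6 libraries also called 130 of the 168, but both fits use the same other 5 libraries, so this overlap is no independent check. The groups did not overlap for 3825 of the 16943 genes (22.6%), where chance gives 10% for 3 against 3.

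Of 40 gene lists, 12 passed the set test with the preset correlation (camera, adjusted p under 0.05), 5 higher and 7 lower, and 0 passed with an estimated correlation. At the preset correlation 5 of the 10 splits of the 6 tumors, the real one among them, gave at least 12 lists. The highest other split gave 18, so the number of calls does not set the real groups apart. A test of each list by itself (fry) put 3 past the threshold: collagens and matrix (adjusted p = 0.0091), erythroid and blood (0.026) and mural cell and fibroblast (0.047). The median log2 fold change of all genes was -0.095, and -0.021 without sgPtk2 tumor 2, so most of that offset came from this library. Camera sets a list against the other genes, so its sign can differ from that of a median. That was so for the YAP/TAZ target, astrocyte, monocyte and macrophage, dendritic cell, cytokine and hypoxia lists, whose medians were below 0 and whose test pointed higher. None of these 6 lists passed, and without sgPtk2 tumor 2 the medians of the YAP/TAZ target (0.063) and cytokine (0.10) lists were above 0 and the test of the astrocyte list pointed lower.

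**Figure D3:**
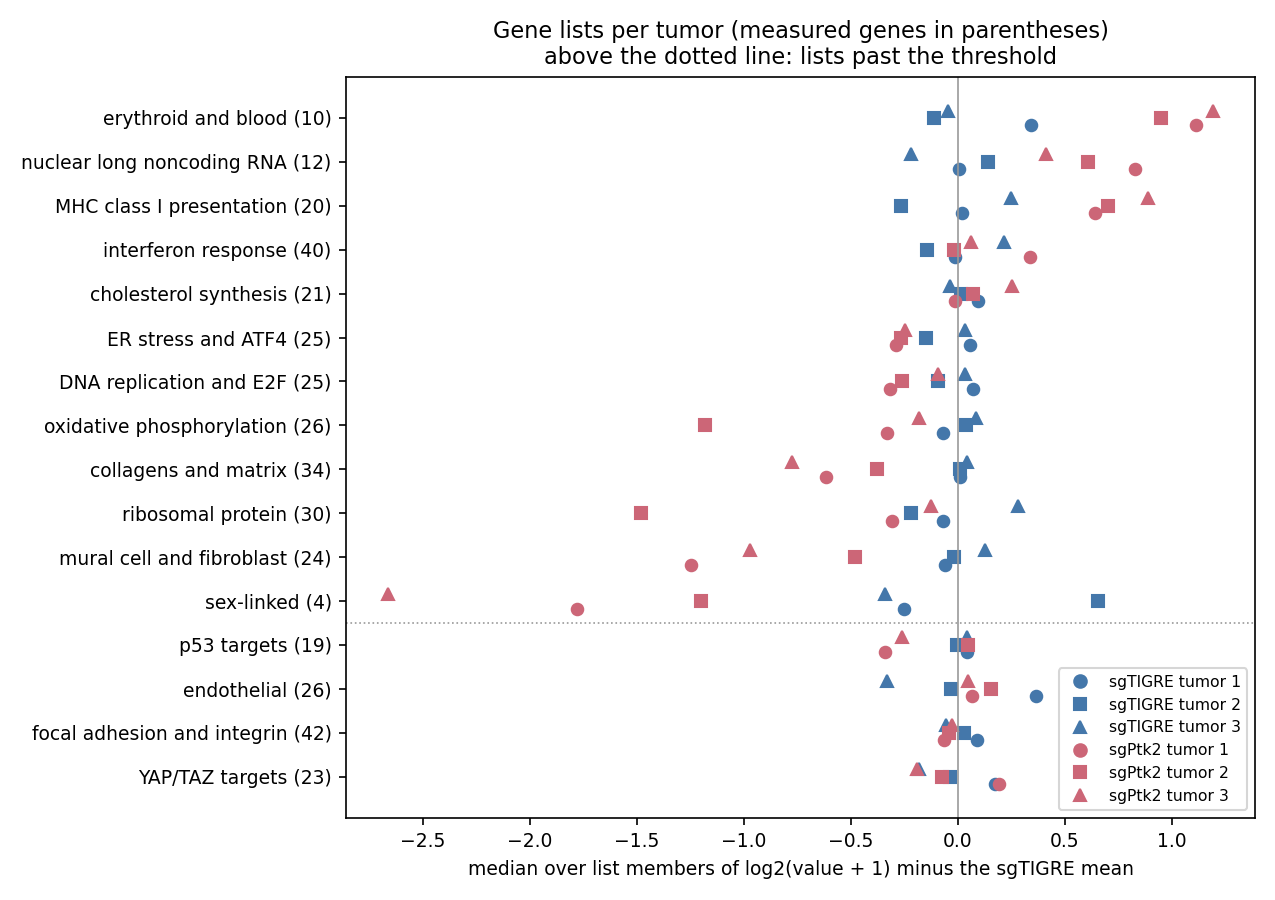
Each point is, for 1 tumor, the median over the measured members of a gene list of log2(value + 1) minus the mean of the sgTIGRE tumors (x axis), with lists on the y axis, sgTIGRE in blue, sgPtk2 in red, and circles, squares and triangles for tumors 1, 2 and 3. The 12 lists above the dotted line passed camera with the preset correlation, and of the ribosomal protein genes sgPtk2 tumor 2 lies at -1.48 against -0.31 and -0.13 in sgPtk2 tumors 1 and 3.

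MHC class I presentation genes rose in the sgPtk2 tumors, with 18 of 20 measured members higher and a median log2 fold change of 0.65, or 1.56-fold (camera, adjusted p = 8.4e-13). The adjusted p was 0.30 with an estimated correlation. The list medians were 0.64, 0.70 and 0.89 in sgPtk2 tumors 1, 2 and 3. Besides Nlrc5, Tap2, a subunit of the peptide transporter of the endoplasmic reticulum, was at 429 ± 109 in sgPtk2 against 137 ± 35.3 in sgTIGRE tumors. The immunoproteasome subunit gene Psmb8 was at 485 ± 65.8 against 205 ± 41.3. The class I heavy chain gene H2-Q6 was at 658 ± 153 against 245 ± 49.5, with reads that its close relatives can share. Adjusted over the list alone, 9 members passed, all higher, and 0 passed over all genes.

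Interferon response genes also rose as a set, by a median of 0.14, with 24 of 40 higher (camera, adjusted p = 0.031, and adjusted p = 0.76 with an estimated correlation). The call ended without sgTIGRE tumor 2 (adjusted p = 0.23) and without sgPtk2 tumor 1 (0.39), and 0 members passed adjusted over the list alone. Without sgPtk2 tumor 2 the call held (camera, adjusted p = 0.0010, and adjusted p = 0.89 with an estimated correlation), and 8 higher and 1 lower member passed adjusted over the list alone. Stat1 was at 439 ± 79.2 against 292 ± 17.8, and the guanylate-binding protein gene Gbp5 at 102 ± 22.05 against 50.5 ± 2.92. Cmpk2 was higher too, at 317 ± 85.7 against 171 ± 15.2, while Ifi27l2a was lower, at 78.8 ± 45.1 against 224 ± 69.5. The MHC class II list, with 4 of 8 genes higher, did not pass (camera, adjusted p = 0.45). The 6 lists of immune cell types did not pass either, with camera adjusted p of 0.20 for B and plasma cells, 0.33 for microglia, 0.42 for neutrophils, 0.45 for T and NK cells and for monocytes and macrophages, and 0.53 for dendritic cells. Within them Irf8, a transcription factor of myeloid cells, was at 393 ± 89.4 against 179 ± 16.4, and the antibody light chain gene Igkc at 238 ± 27.5 against 625 ± 258. Both passed adjusted over their list alone (limma, adjusted p = 0.0062 and 0.011). So did the dendritic cell gene Clec9a and Thbs1 of the monocyte and macrophage list, which were higher, and Sparc, Olfml3 and Tmem119 of the microglia list, which were lower (limma, adjusted p = 0.018, 0.018, 0.0043, 0.023 and 0.025). The call of B and plasma cells as lower arose without sgTIGRE tumor 2 (camera, adjusted p = 0.046), at the preset correlation, and with 6 libraries that list had an adjusted p = 0.76 with an estimated correlation.

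Genes of mural cells, the contractile cells of vessel walls, and of fibroblasts fell in the sgPtk2 tumors. Of 24 measured, 21 were lower, with a median log2 fold change of -1.09, or 2.12-fold (camera, adjusted p = 1.2e-07, and adjusted p = 0.23 with an estimated correlation). The list medians were -1.24, -0.48 and -0.97 in sgPtk2 tumors 1, 2 and 3. Col3a1, a fibrillar collagen chain, was at 1939 ± 652 against 6097 ± 1179, the adhesive glycoprotein gene Vtn at 568 ± 33.2 against 1474 ± 361, smooth muscle actin Acta2 at 151 ± 21.1 against 308 ± 20.7, and the proteoglycan gene Dcn at 83.1 ± 12.5 against 220.2 ± 61.9. Adjusted over the list alone, 14 members passed, all lower. Endothelial genes did not move with them, with 14 of 26 higher and a median of 0.11 (camera, adjusted p = 0.20). The endothelial genes Vwf, at 1057 ± 167 against 408 ± 278, and Kdr, at 416 ± 47.8 against 225 ± 63.9, did not pass. The endothelial list was called higher without sgTIGRE tumor 1 (camera, adjusted p = 0.0029), at the preset correlation, and with 6 libraries it had an adjusted p = 0.76 with an estimated correlation.

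Collagens and other matrix genes fell too, with 28 of 34 lower and a median of -0.55, or 1.46-fold (camera, adjusted p = 3.9e-07, and adjusted p = 0.21 with an estimated correlation). Col1a1, Col1a2 and Col3a1 are also in the mural cell and fibroblast list, and Sparc in the microglia list, so these falls are partly the same. Besides Postn, Col6a1 was at 194 ± 25.7 against 510.1 ± 115, Col6a2 at 184 ± 48.8 against 538 ± 157, and Sparc, a collagen-binding protein gene, at 1069 ± 154 against 2281 ± 229. Adjusted over the list alone, 12 members were lower and 1 higher, and without sgPtk2 tumor 2 these counts were 20 and 3. Thbs1, which encodes thrombospondin, a matrix protein of platelets and stroma, was at 622 ± 215 against 198 ± 34.4.

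Erythroid and blood genes rose, with 8 of 10 measured higher and a median of 1.02 (camera, adjusted p = 0.00015, and adjusted p = 0.22 with an estimated correlation). Alas2, the erythroid enzyme of heme synthesis, was at 86.5 ± 35.0 against 15.9 ± 6.66, and the beta globin genes Hbb-bs and Hbb-bt, which can share reads, at 577 ± 84.2 against 278 ± 93.4 and at 55.4 ± 5.43 against 22.3 ± 4.08. Nuclear long noncoding RNAs rose, with 11 of 12 higher and a median of 0.66 (camera, adjusted p = 0.00013, and adjusted p = 0.30 with an estimated correlation). This rise was not confined to 1 library, with list medians of 0.83, 0.61 and 0.41 in sgPtk2 tumors 1, 2 and 3. Whether it is tied to the changes of other lists was not tested. Rian and Mirg, imprinted noncoding RNAs of one cluster on chromosome 12, were at 2721 ± 328 against 1502 ± 97.5 and at 416 ± 89.4 against 212 ± 21.2. The 4 measured members of the sex-linked list, all on Y, fell by a median of 2.01 on the log2 scale (camera, adjusted p = 0.00027, and adjusted p = 0.34 with an estimated correlation). Ddx3y was at 64.0 ± 30.5 against 262 ± 122 and Kdm5d at 58.4 ± 39.0 against 212 ± 73.5. Xist was at 12.8 ± 10.2 against 6.27 ± 1.35, and at 5.22 to 24.6 in the 6 tumors.

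Ribosomal protein genes fell, with 28 of 30 lower and a median of -0.64 (camera, adjusted p = 0.00016, and adjusted p = 0.76 with an estimated correlation). Most of this lay in sgPtk2 tumor 2, the library with 18.5% of its reads from 7SK, and without it the median was -0.20 and the call ended (camera, adjusted p = 0.10). Oxidative phosphorylation genes fell by a median of 0.53 on the log2 scale (camera, adjusted p = 0.032, and adjusted p = 0.76 with an estimated correlation). That call ended without sgPtk2 tumor 2 (median -0.24, adjusted p = 0.11) and without sgTIGRE tumor 3 (0.065), and the list medians were -0.33, -1.18 and -0.18 in sgPtk2 tumors 1, 2 and 3. Uqcrh was at 398 ± 79.2 against 713 ± 128, while Cox6c was at 1499.5 ± 237 against 979 ± 184. DNA replication genes fell by a median of 0.26, with 19 of 25 lower (camera, adjusted p = 0.030, and adjusted p = 0.76 with an estimated correlation). That call ended without sgTIGRE tumor 1 (adjusted p = 0.081) and without sgPtk2 tumor 1 (0.14). Uhrf1 was at 1223 ± 440.4 against 2135 ± 229.9 and Rfc4 at 232 ± 25.9 against 384 ± 33.9. The mitosis list did not pass (camera, adjusted p = 0.16), and was called lower without sgPtk2 tumor 1 (0.026) and without sgPtk2 tumor 3 (0.011), at the preset correlation. With 6 libraries it had an adjusted p = 0.87 with an estimated correlation. Its medians were -0.044, -1.08 and 0.13 in sgPtk2 tumors 1, 2 and 3, and without tumor 2 its median log2 fold change turned from -0.30 to 0.063.

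Genes of endoplasmic reticulum stress and ATF4 fell, with 20 of 25 lower and a median of -0.22 (camera, adjusted p = 0.040, and adjusted p = 0.54 with an estimated correlation). Phgdh was the 1 member to pass adjusted over the list alone, against 2 members without sgPtk2 tumor 2, and the transcription factor gene Atf5 was at 277 ± 129 against 589 ± 31.8. Without sgPtk2 tumor 2 the log2 fold change of Atf5 moved from -1.21 to -0.80. The call ended without sgTIGRE tumor 1 (adjusted p = 0.093), sgTIGRE tumor 3 (0.099), sgPtk2 tumor 1 (0.15) or sgPtk2 tumor 3 (0.22). It also ended with the tumor numbers as a block. Cholesterol synthesis genes rose, with 13 of 21 higher and a median of 0.078 (camera, adjusted p = 0.033, and adjusted p = 0.76 with an estimated correlation). Sqle, squalene epoxidase, was at 571 ± 18.9 against 327 ± 13.5 and passed adjusted over the list alone. This call ended without sgTIGRE tumor 3 (adjusted p = 0.11), sgPtk2 tumor 2 (0.062) or sgPtk2 tumor 3 (0.26). Sqle and Cox6c lie on chromosome 15, between the start of the chromosome and Ptk2.

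The lists closest to focal adhesion kinase did not pass. Of 42 focal adhesion and integrin genes, 17 were higher and 25 lower, with a median of -0.13, and -0.076 without sgPtk2 tumor 2 (camera, adjusted p = 0.87 and 0.70). The integrin gene Itga3 was at 214 ± 10.4 against 122 ± 6.85, and Parva, a partner of integrin-linked kinase, at 222 ± 58.3 against 399 ± 61.0, and 0 members passed adjusted over the list alone. Of 23 targets of the coactivators YAP and TAZ, 10 were higher and 13 lower, with a median of -0.056 and a mean of 0.024 (camera, adjusted p = 0.54). Without sgPtk2 tumor 2 their median turned to 0.063, with 12 higher and 11 lower (adjusted p = 0.62). Nt5e, the ectonucleotidase CD73, was at 230.2 ± 34.3 against 87.9 ± 26.9 and was the 1 member past the threshold adjusted over the list alone, against 2 higher and 1 lower without that tumor. The MAPK output list (adjusted p = 0.30) and the immediate early genes (0.87) did not pass camera, and the median of the MAPK list turned from 0.095 to -0.081 without sgPtk2 tumor 2.

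Targets of p53 did not pass with 6 libraries, with 12 of 19 lower and a median of -0.19 (camera, adjusted p = 0.11). They were called lower without sgPtk2 tumor 2 (median -0.33, camera, adjusted p = 0.0073, and adjusted p = 0.42 with an estimated correlation). The tumors are of a Trp53 null genotype, so this cannot be read as lower p53 activity in the tumor cells. What lowered these genes was not tested. Adjusted over the list alone, 4 members passed with 6 libraries, all lower. Ccng1 was at 417 ± 17.2 against 781 ± 38.0, Cdkn1a, the cyclin-dependent kinase inhibitor p21, at 829 ± 103 against 1401 ± 176, Eda2r at 43.5 ± 2.89 against 113 ± 30.1, and Gdf15 at 133 ± 52.1 against 271 ± 47.3. Mature oligodendrocyte genes, at a median of -0.62 with 13 of 15 lower, did not pass (camera, adjusted p = 0.080). That list was called lower without sgPtk2 tumor 2 (adjusted p = 0.025), sgPtk2 tumor 1 (0.036), sgTIGRE tumor 1 (0.025) or sgTIGRE tumor 3 (0.0071). With an estimated correlation it did not pass with 6 libraries (adjusted p = 0.76) or without sgPtk2 tumor 2 (0.89). Lists of oligodendrocyte progenitors, neural progenitors, astrocytes and neurons did not pass (camera, adjusted p = 0.54, 0.21, 0.97 and 0.49), and without sgTIGRE tumor 3 those of neural progenitors (0.036) and neurons (0.018) were called lower at the preset correlation. With 6 libraries these 2 lists had adjusted p = 0.76 and 0.87 with an estimated correlation. The mesenchymal list did not pass (adjusted p = 0.33), and its member Runx1 was at 519 ± 134 against 149 ± 46.1 and passed adjusted over that list alone.

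The other lists did not pass. The camera adjusted p was 0.35 for cytokines and NF-kB, 0.53 for hypoxia and glycolysis, 0.94 for receptor tyrosine kinases, 0.54 for glioma synapse genes and 0.54 for skeletal muscle and skin. It was 0.53 for ependymal and choroid plexus genes, 0.53 for mitochondrially encoded genes and 0.49 for replication-dependent histones. Without sgPtk2 tumor 1 the ependymal (adjusted p = 0.011) and mitochondrially encoded (0.019) lists were called lower, and without sgTIGRE tumor 3 the histones were called higher (0.0075), all at the preset correlation. With 6 libraries each of these 3 lists had an adjusted p = 0.87 with an estimated correlation.

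Genes of 7 of the 21 chromosomes passed as sets (camera, adjusted p under 0.05). Chromosomes 1 and 12 were higher, with medians of 0.096 and 0.078, and chromosomes 7, 13, 17, 19 and Y lower, with medians of -0.25, -0.27, -0.24, -0.21 and -2.03. Without sgPtk2 tumor 2 the median of chromosome 12 was 0.17, as that tumor was at -0.016 and sgPtk2 tumors 1 and 3 at 0.16 and 0.17. The adjusted p ran from 0.00025 for the 5 measured genes of Y to 0.036 for chromosome 19, and with an estimated correlation 0 chromosomes passed, the smallest adjusted p being 0.19. The 4 measured genes of the sex-linked list are among those of Y, so these calls rest on the same genes. Without sgPtk2 tumor 1 or without sgPtk2 tumor 3 the count was 4, and with no filter on the genes it was 1.

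Chromosome 15 as a whole did not pass (camera, adjusted p = 0.67), but its genes split at Ptk2, in a pattern chosen after its values were seen. The 202 measured genes before Ptk2 had a median log2 fold change of 0.32, with 77.7% higher, and the 421 after it a median of -0.24, with 29.7% higher. The step was 0.56 (95% bootstrap interval over genes 0.48 to 0.66), and 0.65 (0.57 to 0.71) without sgPtk2 tumor 2. Each sgPtk2 tumor showed it, with steps of 0.79, 0.47 and 0.53 in tumors 1, 2 and 3. Each sgTIGRE tumor against the mean of the other two gave -0.011, 0.18 and -0.25. Ago2, the Argonaute gene next to Ptk2, was at 2397 ± 219 in sgPtk2 against 1228 ± 114 in sgTIGRE tumors and was chosen after its values were seen. On chromosome 9, which carries TIGRE, the step at the neighboring gene Carm1 was 0.089 (-0.052 to 0.19).

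**Figure D4:**
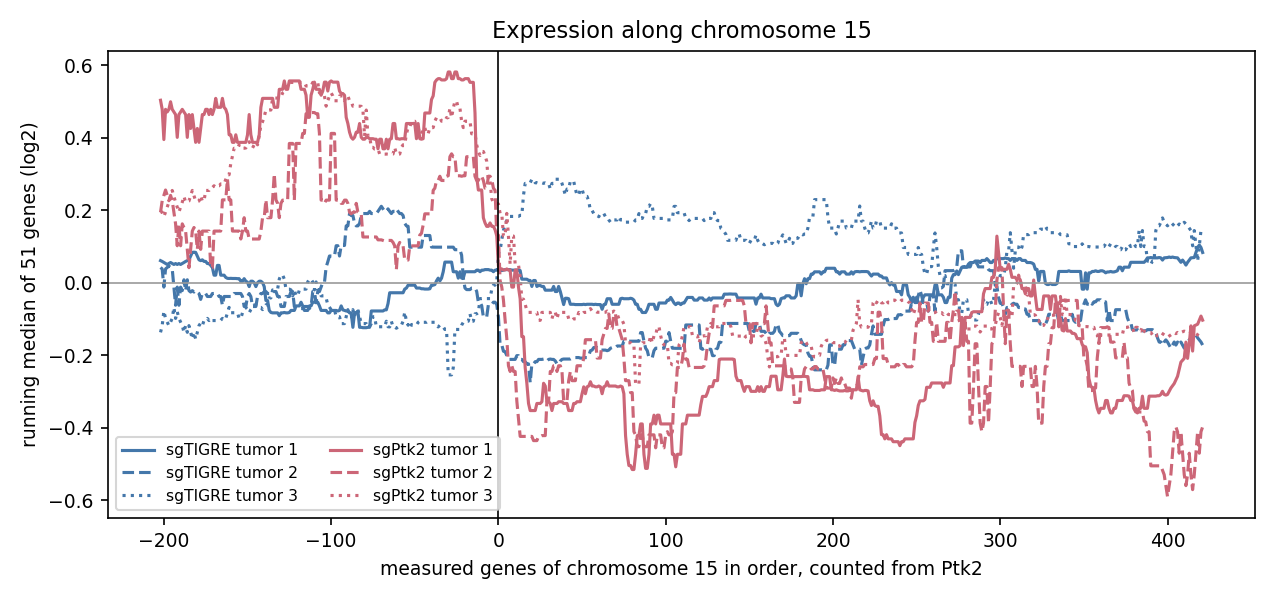
Running median over 51 neighboring genes of the log2 difference (y axis) along the measured genes of chromosome 15 in order, counted from Ptk2 at 0 (x axis, vertical line), with each sgPtk2 tumor (red) set against the mean of the sgTIGRE tumors and each sgTIGRE tumor (blue) against the mean of the other two. The sgPtk2 tumors have medians of 0.51, 0.23 and 0.41 before Ptk2 and -0.28, -0.24 and -0.12 after it.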

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

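The 12 list calls and 7 chromosome calls stayed within 1.5 times those counts under the other scalings and pseudocounts run. The pseudocounts, TMM scaling in limma, a mean filter, library weights, removal of regional medians and the count tests without sgPtk2 tumor 2 were chosen after seeing the data. Genes past the threshold, 0 in limma with 6 libraries, ranged from 0 to 168 when 1 library was left out, 168 without sgPtk2 tumor 2 and 4 without sgPtk2 tumor 3. They numbered 26 with no filter, 15 at an adjusted p under 0.1, 442 with voom and quality weights, 1624 with library weights, 574 in DESeq2 and 734 in DESeq2 without sgPtk2 tumor 2. In edgeR they numbered 7 with RLE factors, 8 with the robust fit, 1336 with no filter and 103 without sgPtk2 tumor 2. The library weights were 0.114 for sgPtk2 tumor 2 and 8.46 for sgTIGRE tumor 1. Ptk2 ranged from -0.88 to -0.67 with 1 library left out. It passed at -0.88 without sgPtk2 tumor 2, -0.87 with library weights, -0.75 in DESeq2, -0.84 with voom, -0.79 in edgeR with no filter, -0.87 in edgeR without sgPtk2 tumor 2 and -0.89 in DESeq2 without it. Lists past the threshold numbered 0 with an estimated correlation and 3 with fry, and 11 to 13 with 1 library left out. Chromosomes numbered 1 with no filter, 0 with an estimated correlation and 4 to 10 with 1 library left out. With 1 library left out Pten ranged from -0.11 to 0.18 and Trp53 from -0.099 to 0.32. Pten turned sign at -0.020 with TMM, -0.0060 with library totals, -0.027 with TMM after abundant RNA was left out, -0.079 without sgTIGRE tumor 3, -0.11 without sgPtk2 tumor 3, -0.17 with library weights, -0.058 with voom and -0.0052 in edgeR with no filter. Trp53 turned at -0.099 without sgPtk2 tumor 2, -0.10 with library weights, -0.11 with voom, -0.083 in edgeR and -0.11 in DESeq2 without that tumor. Otx2, at -0.076 and from -0.23 to 0.19 with 1 library left out, turned at 0.19 without sgPtk2 tumor 2, 0.15 with library weights, 0.093 with voom, 0.20 in edgeR and 0.18 in DESeq2 without that tumor. The cause of these turns was not tested. With the tumor numbers as a block, limma called 0 genes and 12 lists, Ptk2 had an adjusted p of 0.33 and the endoplasmic reticulum stress call ended (0.072). The numbers do not pair the tumors by the design. Deviations of same-numbered tumors correlated at 0.12, 0.065 and 0.10, and 6 of 6 libraries correlated best with their own number, a hint from the data only. Each pair counts from both sides and the deviations sum to 0 within a group, so these 6 matches are not independent. Blocked by column numbers the counts were 0 genes and 13 lists. At 1669353 reads in all, 1 read in sgPtk2 tumor 2 is worth 3.82, which limits what low genes can show there.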

Other observations

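The tests of GC content and transcript length, of the scan for steps, of mural against fibroblast markers and of other splits were set before their results were seen, and the tests of the segment boundary, of called genes near Ptk2, of MHC copies, immune cells and strain, of vessels and of photoreceptor and pineal genes were chosen after.

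Many photoreceptor genes were abundant in these tumors and lower with the Ptk2 guide. Of 44 measured genes, from a list of 51 written after such genes were noticed, 40 were lower in sgPtk2 tumors, with a median log2 fold change of -0.81, and -0.77 without sgPtk2 tumor 2. Since the list was written from what these values showed, a test of it on them restates the observation (camera, adjusted p = 2.9e-12, and 9.1e-12 without that tumor, and adjusted p = 0.29 and 0.42 with an estimated correlation). Whether the set stands apart from others is left open. The list medians were -0.87, -1.25 and -0.48 in sgPtk2 tumors 1, 2 and 3. A list of pineal genes had 7 of 10 measured lower and did not pass (camera, adjusted p = 0.31).

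Among these genes, Gnat2, the cone transducin subunit, was at 492 ± 61.2 against 1121 ± 264, Slc24a1, the rod sodium-calcium exchanger, at 60.7 ± 33.7 against 347 ± 82.4, and Aipl1, a photoreceptor chaperone, at 709 ± 51.5 against 1249 ± 207 (SD, n = 3 each). Crx, a transcription factor of photoreceptor and pineal cells, was at 2433 ± 846 against 3859 ± 399.8, and Tph1, an enzyme of serotonin synthesis, at 2328 ± 503 against 3893 ± 793, where the median tested gene was at 127. Without sgPtk2 tumor 2 the log2 fold change of Crx moved from -0.72 to -0.46, so much of its difference rested on that library. Otx2, a transcription factor of the same cells and a member of the list, did not go with the others, at 1976 ± 578 against 2023 ± 226 (log2 fold change -0.076, and 0.19 without sgPtk2 tumor 2). Not all photoreceptor genes were abundant, and Rcvrn, which encodes recoverin, was at 6.69 ± 3.67 in sgTIGRE and 0.89 ± 0.95 in sgPtk2 tumors, too low to be tested. Among progenitor genes chosen after their values were seen, Olig2, Sox10 and Sox2 were low too. They were at 4.51 ± 3.34, 6.73 ± 9.06 and 14.9 ± 10.7 in sgTIGRE and 6.09 ± 5.42, 6.53 ± 2.82 and 9.56 ± 8.45 in sgPtk2 tumors. Other members of their lists were not low, as Dll1 was at 1002 ± 125 in sgTIGRE tumors. Gfap of the astrocyte list was at 186 ± 164 in sgTIGRE and 466 ± 153 in sgPtk2 tumors.

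The protocadherin beta genes, a cluster of neuronal adhesion genes on chromosome 18, were higher in sgPtk2 tumors for 21 of 21 measured members, with a median log2 fold change of 1.29, and 1.30 without sgPtk2 tumor 2. This family was chosen because its values were seen to be high, so no test of it on these values is given. List medians were 1.14, 1.09 and 1.27 in sgPtk2 tumors 1, 2 and 3. Besides Pcdhb6, Pcdhb19 was at 139 ± 5.38 against 51.6 ± 12.6 and Pcdhb14 at 102 ± 5.72 against 30.0 ± 11.8, and members can share reads. In the neighboring alpha and gamma clusters 22 of 35 were higher, with a median of 0.20 (-0.060 to 0.52).

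Expression along chromosome 15 stepped down at Ptk2 in the sgPtk2 tumors, and a candidate explanation is gain or loss of a segment that ends at the cut. The step was 0.47 (0.38 to 0.56) after the trend on GC content and transcript length was removed, which argues against that trend as the whole cause. With 50 genes on each side the step was 0.76, and 0.41% of 14487 scanned positions had one as large, which argues against a step common along the genome. Windows of neighboring positions share genes, so the positions are not independent and this share is no chance rate. The largest step, -1.08, lay elsewhere, at Ankhd1 on chromosome 18 near the protocadherin clusters. In the region of Ptk2 the largest was 0.86, at Trappc9, and the next region, at Adra1b on chromosome 11, had -0.52. The best boundary lay at -1, 2 and -1 measured genes from Ptk2 in sgPtk2 tumors 1, 2 and 3 set against the mean of the sgTIGRE tumors, and at -1, 20 and -1 set against the sgTIGRE tumor of the same number, where simulated steps of 0.4 were placed within 5 genes in 37 of 60 cases. In sgTIGRE tumors 1, 2 and 3, each set against the other sgTIGRE tumors, it lay at -157, -5 and -5 with steps of -0.011, 0.18 and -0.25, and since tumors 2 and 3 are in each other's reference these count as 1 observation, so whether the place is specific to the cut is left open.

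Without sgPtk2 tumor 2, 5 of the 202 genes before Ptk2 were called (2.48%) against 163 of 16741 elsewhere (0.97%), a difference that did not pass (two-sided Fisher's exact p = 0.051, over genes that are not independent).

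Several explanations could account for the higher MHC class I genes. Genes of the MHC region outside the list had a median of -0.31 (-0.41 to -0.22), which argues against more copies of that region, and members on other chromosomes had a median of 0.50 (-0.041 to 0.74), and without sgPtk2 tumor 2 of 0.54 (0.38 to 0.76), which argues the same way only without that tumor. Genes of 6 immune cell lists pooled (63 measured) had a median of -0.087 (-0.25 to 0.094), below the 0.65 (0.31 to 1.18) of the class I list. For the genes measured, that argues against more immune cells of all types alike. Some types were thinly covered, with 11 of 32 T and NK cell, 5 of 16 B and plasma cell, 4 of 15 neutrophil and 8 of 15 dendritic cell genes. The pool also holds the matrix genes Sparc, which fell, and Thbs1, which rose. Members that are not H2 genes had a median of 0.63 (0.28 to 1.35), which argues against sequence differences of the H2 genes themselves between strains as the whole cause. Of the 20 members, 13 lie on chromosome 17 and only 8 are H2 genes, so some of the others share that chromosome. A strain difference that covers such linked members is therefore left open by this value. A response to the loss of Ptk2 stays open as a hypothesis, as does a change in 1 immune cell type, and neither was tested.

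The lower matrix, mural and fibroblast genes could reflect fewer stromal cells. The endothelial list had a median of 0.11 (-0.18 to 0.43) against -1.09 (-1.31 to -0.77), which argues against a loss of vessels and stroma as a whole. Mural markers had a median of -1.02 (-1.34 to -0.22) and fibroblast markers -1.26 (-1.70 to -0.86), and with all 6 libraries the interval of the mural markers reaches above -0.3, which leaves fewer cells of both kinds open. Without sgPtk2 tumor 2 they were -0.87 (-1.47 to -0.66) and -1.41 (-1.73 to -1.17), both below -0.3, as fewer cells of both kinds would give. The 12 mural and 10 fibroblast markers are parts of the 24 genes already found lower on these values. Low medians of both were therefore likely in advance and are no independent support. Lower expression per cell would give the same medians and was not tested.

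The 6 tumors can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes and the highest other 0, so that 10 splits gave as many (2068 genes at an unadjusted p under 0.05 against at most 677 in the others). For lists the real split gave 12 and the highest other 18, with 5 splits as large, and for chromosomes 7 against 4, with 1 split, the real one, as large.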
